A study of Mus musculus with 20 samples.

How the data were processed

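The study purified neuronal nuclei from male mice by INTACT, in which a Cre driver turns on a GFP-tagged nuclear envelope protein (Sun1-GFP) in chosen cells and the tagged nuclei are captured from the tissue. Nuclei of cortical GABAergic, cortical glutamatergic and cerebellar Purkinje neurons came from wild-type mice, and nuclei of both cortical classes came also from mice labelled MeCP2 KO. Per the labels, the nuclei of each mouse were divided between DNA, for whole-genome bisulfite sequencing, and RNA, for RNA sequencing. Here 10 RNA libraries were analysed, 2 biological replicates in each of 5 groups, and the 10 bisulfite libraries were not analysed here. Mice were 6 to 7 weeks old, except GABAergic wild-type replicate 1 and GABAergic MeCP2 KO replicate 2, which came from mice of 5 to 6 weeks.

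The deposited table held a whole-number count of reads per gene for each library, with 33924 genes and 0 columns that matched no sample. RNA was depleted of ribosomal RNA and made into strand-specific total-RNA libraries read as paired ends, per the labels' protocols, so that unspliced and non-polyadenylated nuclear RNA could contribute to the counts. The submitters' processing notes name cutadapt 2.10, Bismark 0.19.0, TopHat2 2.1.1, featureCounts 1.5.3, edgeR 3.32.1, DESeq2 1.30.1 and the mouse genome build mm9, with no role or order for each. The gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Counts of overlapping genes, of antisense genes such as Dlx6os1 and of near-identical copies such as Il22 and Iltifb are therefore uncertain, since reads of one could have been given to another. Counts cover whole genes, and do not show which exons carried the reads.

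Library totals ranged from 7346883 to 15795554 counts. Genes were kept with the filterByExpr function of edgeR and the 5 groups, which left 19822 genes. Libraries were scaled with TMM. Normalized levels are TMM-scaled CPM, given as mean ± SD with n = 2 libraries, unless a single library is named. All 10 libraries entered a single edgeR quasi-likelihood fit with robust dispersion and 1 mean per group, which left 5 residual degrees of freedom and gave a common biological coefficient of variation of 0.162. Differential expression p-values came from the quasi-likelihood F test, were adjusted by the Benjamini-Hochberg method over the genes tested, and were called at an adjusted p below 0.05. These p-values are 2-sided. A rank-based permutation test could not serve, because 2 libraries against 2 cannot give a p under 0.333. R 4.3.3 was used with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

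The contrasts tested were glutamatergic against GABAergic wild type, Purkinje against each cortical wild type, MeCP2 KO against wild type in each cortical class, and the difference between these last effects (glutamatergic minus GABAergic). A fold change was computed against a floor of 3 counts over a group when both libraries of that group held 0 counts, and is then a lower bound. With 1 to 3 counts in a group, the ratio of TMM-scaled counts is given with an exact 95% counting interval. These bounds and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

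Gene lists were written before the data were examined. They cover GABAergic identity, glutamatergic identity, Purkinje identity, interneuron subclass, cortical layer, cerebellar granule and other cerebellar neurons, striatal and subcortical neurons, astrocyte and Bergmann glia, oligodendrocyte, oligodendrocyte precursor, microglia, endothelial and mural cells, immediate early genes, GABA-A receptor subunits, ionotropic glutamate receptors, voltage-gated potassium channels, voltage-gated calcium and sodium channels, synaptic adhesion, DNA methylation machinery, MeCP2 partners and Rett-related genes, reported MeCP2-responsive genes, neurodevelopmental disorder genes, oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins and sex-linked controls. Some genes stand in several lists. Of 588 entries, 586 were found, 7 of them through a synonym. Each of the 26 lists was tested with camera, which asks whether the members of a list stand higher or lower than the other genes, at its preset inter-gene correlation of 0.01 and a minimum of 5 tested members. Camera p-values were adjusted over the 156 tests of 26 lists in 6 contrasts. Camera was also run with the correlation estimated from the residuals. For each list the counts of members past the threshold are given over all genes tested and adjusted over the list alone.

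The named genes follow a rule fixed before the data were examined. It takes Mecp2 and the Cre driver genes Gad2 (written Cad2-cre in the labels), Camk2a and Pcp2; then, for each comparison, the 8 largest positive and the 8 largest negative log2 fold changes among genes past the threshold with at least 5 CPM in the higher group and no overlap between the libraries of the groups, with genes named only by a clone or model number (Gm, Rik, LOC) passed over; and in each list up to 4 members past the threshold with the largest changes and up to 2 others with the highest CPM. Genes named outside this rule are marked as chosen after their values were seen.

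Gene spans for the test of long genes, gene neighbours and synonyms came from a RefSeq table of assembly GRCm38.p6. Because this differs from the mm9 build of the processing notes, no coordinates are given. A span was found for 17598 of the tested genes (88.8%). Genes with a span over 100 kb were compared with the other genes, with limits of 50 and 200 kb as alternatives.

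The differential test, camera and the long-gene test were tested on simulated counts drawn for the real genes, with 200 genes changed, 50 at each of 4 fold changes (1.5, 2, 4 and 8). In the simulated GABAergic MeCP2 KO comparison of 19849 genes, the edgeR test recovered 6% of genes changed 1.5-fold, 44% at 2-fold, 92% at 4-fold and 96% at 8-fold, and 8.46% of its calls were false. In the simulated glutamatergic comparison of 19877 genes these were 10%, 54%, 92% and 96%, with 11.3% false calls. For the simulated difference of both effects they were 2%, 22%, 74% and 86%, with 12.4% false calls among 19877 genes. In the simulated comparison of glutamatergic with GABAergic wild type, 63.5% of the changed genes were recovered with 6.62% false calls among 19896 genes.

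Alternatives fixed before the data were examined were DESeq2 size factors and library size alone as scalings, no filter beyond 1 count in 1 library, a stricter filter of 1 CPM in 2 libraries with a total of 50 counts, a test against a log2 fold change of 0.5 (glmTreat), DESeq2 and limma-voom as tools, a fit of only the groups compared, the replicate number as a block, an age term in the GABAergic MeCP2 KO comparison, each library left out in turn, other span limits, and an estimated inter-gene correlation. Leaving out a library leaves its group with a single library, which is then assumed to vary like the other groups. Added after the data were seen were fits of the 8 cortical libraries alone, the age term in the other contrasts, the average KO effect over both cortical classes, and the gene lists under the other scalings, the cortical fit and the age term.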

Results

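RNA was sequenced from sorted nuclei of 3 neuron classes: cortical GABAergic neurons, which release the inhibitory transmitter GABA, cortical glutamatergic neurons, which are excitatory, and Purkinje neurons, the inhibitory output neurons of the cerebellar cortex. Both cortical classes were also collected from male mice labelled MeCP2 KO. MeCP2 is a protein that binds methylated DNA and is mutated in Rett syndrome. Each of the 5 groups held 2 biological replicates. Library totals were 14473932 and 14127391 counts in GABAergic wild type, 15795554 and 14610697 in GABAergic MeCP2 KO, 13683883 and 13460051 in glutamatergic wild type, 13603363 and 9693666 in glutamatergic MeCP2 KO, and 7346883 and 13040933 in Purkinje wild type. Between 22472 and 25200 genes had at least 1 count in a library. The first principal component of log2 CPM held 66.0% of the variance and the second 18.4%, and the correlation of log2 CPM between the replicates of a group, across genes, was 0.974 to 0.989.

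The targeted gene did not fall in the libraries labelled MeCP2 KO. Mecp2 had 3396 and 3898 counts in the GABAergic libraries labelled MeCP2 KO against 2123 and 2067 in wild type, and 3995 and 2534 in the glutamatergic libraries labelled MeCP2 KO against 1895 and 1873. In TMM-scaled CPM this was 228 ± 37.5 against 135 ± 0.75 in GABAergic nuclei and 273 ± 17.8 against 135 ± 2.65 in glutamatergic nuclei (mean ± SD, n = 2 libraries per group). Purkinje wild type held 119 ± 8.88 CPM. The log2 difference for Mecp2 was 0.76 (SE 0.14, adjusted p = 0.397) in GABAergic and 1.01 (SE 0.14, adjusted p = 0.0925) in glutamatergic nuclei, neither past the threshold of the edgeR quasi-likelihood test. Without glutamatergic wild-type replicate 2 the glutamatergic difference passed, at an adjusted p of 0.0467, and DESeq2 called Mecp2 higher in both classes (adjusted p = 0.0015 and 1.6e-06). The counts cover the whole gene and the labels do not say which part was deleted, so reads from outside a deleted part may leave the count unable to check the genotype. For this reason the text speaks of libraries labelled MeCP2 KO, and every direction given for them rests on the labels.

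**Figure D1:**
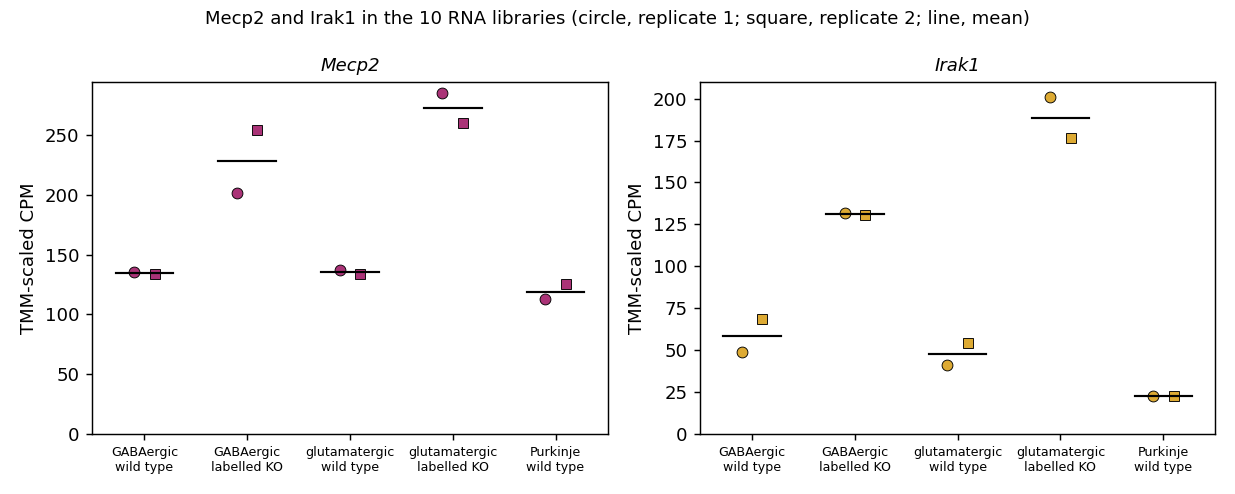
TMM-scaled CPM of Mecp2 and of its neighbour Irak1 in each of the 10 RNA libraries, with points for libraries and lines for group means. Mecp2 lay between 202 and 286 CPM in the 4 libraries labelled MeCP2 KO and at or below 137 CPM in the 4 cortical wild-type libraries.

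The genes taken as Cre drivers followed the sorted classes. The labels write the GABAergic driver as Cad2-cre, which was read as Gad2. Gad2, which encodes a GABA-synthesizing enzyme, was at 247 ± 9.02 CPM in GABAergic wild type, 171 ± 17.6 in Purkinje wild type and 43.7 ± 5.60 in glutamatergic wild type. Camk2a, a kinase of excitatory synapses, was at 1119 ± 259 CPM in glutamatergic, 353 ± 112 in GABAergic and 116 ± 7.20 in Purkinje wild type. Pcp2, a Purkinje cell protein, was at 399 ± 1.24 CPM in Purkinje wild type, 5.10 ± 0.25 in glutamatergic and 2.70 ± 0.58 in GABAergic wild type. In the libraries labelled MeCP2 KO, Gad2 was at 244 ± 3.76 CPM in GABAergic and 52.2 and 29.8 in the glutamatergic libraries, and Camk2a at 288 ± 35.5 and 786 ± 61.4.

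**Figure D2:**
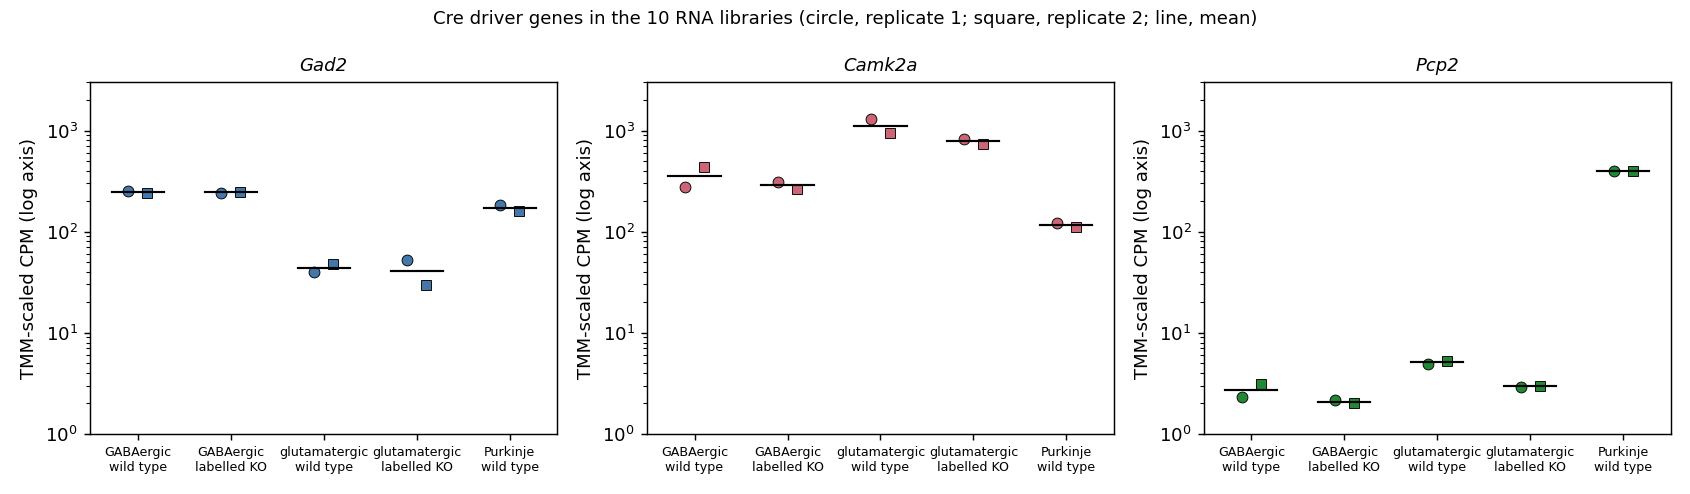
TMM-scaled CPM, on a log axis, of Gad2, Camk2a and Pcp2, the genes taken as Cre drivers, in each of the 10 RNA libraries, with points for libraries and lines for group means. Pcp2 reached 399 ± 1.24 CPM in Purkinje wild type and 2.70 ± 0.58 in GABAergic wild type, and Camk2a was highest in the glutamatergic libraries.

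Glutamatergic and GABAergic wild-type nuclei, both given as cortical, were compared to find the genes that set these classes apart. Most glutamatergic identity and immediate early genes were higher in glutamatergic nuclei, and most GABAergic identity and interneuron subclass genes were lower. The edgeR test called 3282 of 19822 genes, 1622 higher and 1660 lower in glutamatergic nuclei, and 2035 of them differed by more than 1 on the log2 scale. Among the strongest, Satb2, a transcription factor of cortical projection neurons, was at 125 ± 35.0 against 12.4 ± 4.39 CPM, and Vip, an interneuron peptide, at 2.41 ± 0.078 against 61.3 ± 2.05 CPM (log2 fold change −4.66, adjusted p = 4.1e-06).

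All 18 GABAergic identity genes were lower in glutamatergic nuclei, also when adjusted over the list alone, with a median log2 fold change of −3.17 (camera adjusted p = 1.1e-34, adjusted p = 0.105 with an estimated correlation). Gad1, the main GABA-synthesizing enzyme, was at 58.7 against 473 CPM, and Erbb4, a neuregulin receptor of interneurons, at 33.8 against 588 CPM. Lhx6, Dlx6 and Dlx5, transcription factors of interneuron development, had log2 fold changes of −4.21, −3.32 and −2.91. Of 20 glutamatergic identity genes, 18 were higher and 2 did not pass, with the same counts adjusted over the list alone (median 1.92, camera adjusted p = 2.3e-21, adjusted p = 0.101 with an estimated correlation). Neurod1, Neurod2, Neurod6 and Tbr1, transcription factors of excitatory neurons, were higher by 3.26, 2.78, 2.74 and 2.51, while Camk2d (0.18) and Lmo3 (0.06) did not pass. Among 25 interneuron subclass genes 19 were lower and 2 higher (21 and 2 adjusted over the list alone), with a median of −2.43 (camera adjusted p = 4.2e-25, adjusted p = 0.101 with an estimated correlation). Chat, the acetylcholine-synthesizing enzyme, had a log2 fold change of −4.10, and Reln, a secreted glycoprotein, of −1.88. Pthlh had 2 counts in glutamatergic and 86 in GABAergic nuclei, a ratio of 38.5 (95% interval 10.3 to 323).

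Immediate early genes, which neurons transcribe within minutes of activity, were higher in glutamatergic nuclei for 15 of 20 members and lower for 0 (17 and 0 adjusted over the list alone), with a median of 1.29 (camera adjusted p = 8.5e-15, adjusted p = 0.101 with an estimated correlation). Arc, a regulator of synaptic plasticity, was at 230 ± 22.7 against 55.7 ± 0.70 CPM. The nuclear receptor gene Nr4a2 was higher by 2.52 and the transcription factor gene Egr3 by 1.83, while Junb (0.73, adjusted p = 0.083) and Fos (0.66, adjusted p = 0.0805) did not pass.

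Cortical layer genes, which mark projection neurons of particular layers, were higher for 9 and lower for 3 of 23 members (12 and 4 adjusted over the list alone), with a median of 0.52 (camera adjusted p = 0.00058, adjusted p = 0.201 with an estimated correlation). Fezf2, a transcription factor of deep-layer projection neurons, was at 18.4 ± 5.49 against 2.29 ± 1.08 CPM, and Rspo1 (log2 fold change 2.49) and Lhx2 (2.34) were also higher, while the abundant members Rasgrf2 (0.03) and Cux1 (0.63) did not pass. The 8 largest increases outside the lists also held Serinc2 (19.6 ± 0.54 against 0.97 ± 0.29 CPM), Xirp2 (69.7 ± 20.7 against 5.93 CPM), Hkdc1 (32.6 ± 3.24 against 2.75 CPM), Ovol2 (3.85), Dkkl1 (3.42) and Tbata (3.33). The largest decreases held Nxph1 (6.70 against 167 ± 16.9 CPM), Kcnmb2 (1.00 against 27.3 CPM), Th, the dopamine-synthesizing enzyme (0.36 against 12.4 ± 6.35 CPM), Eya4 (−4.85), Frmd7 (−4.59) and Crhbp (−4.46).

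Genes for receptors, channels and adhesion proteins differed in both directions between the cortical classes. Ionotropic glutamate receptor genes were lower for 5 and higher for 1 of 18 members (5 and 2 adjusted over the list alone, median −0.26, camera adjusted p = 0.0490, adjusted p = 0.517 with an estimated correlation). Grin2d, Grik1 and Grin3a had log2 fold changes of −2.26, −2.21 and −1.66, while Gria2, the subunit that limits calcium entry, did not pass (0.03). Of 15 GABA-A receptor genes 3 were lower and 0 higher, also when adjusted over the list alone (median −0.05, camera adjusted p = 0.219), led by Gabrg1 (−1.61) and Gabrg3 (−1.22).
Voltage-gated potassium channel genes were higher for 6 and lower for 7 of 25 members (8 and 8 adjusted over the list alone, camera adjusted p = 0.974). Kcns3 and Kcna5 had log2 fold changes of −3.03 and −1.88, and Kcnc4 and Kcnh5 of 1.58 and 1.26. In this list the median was 0.08 while the mean and the test pointed down. Among 21 calcium and sodium channel genes 6 were higher and 3 lower (8 and 3 adjusted over the list alone, median 0.12, camera adjusted p = 0.396). Cacna2d2, Scn4b and Cacna1g had log2 fold changes of −2.58, −1.37 and 1.01. Synaptic adhesion genes were higher for 5 and lower for 6 of 27 members (6 and 6 adjusted over the list alone, median 0.10, camera adjusted p = 0.702), with Ptprd at 1678 against 693 CPM and Cntnap4 at −2.39. Neurodevelopmental disorder genes were higher for 10 and lower for 2 of 34 members (11 and 2 adjusted over the list alone, median 0.20, camera adjusted p = 0.0483, adjusted p = 0.597 with an estimated correlation), with Shank2, a postsynaptic scaffold, at 1.46. Reported MeCP2-responsive genes were higher for 4 and lower for 8 of 25 members (6 and 11 adjusted over the list alone, median −0.27, camera adjusted p = 0.059).

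Few genes that write, read or remove DNA methylation passed between the cortical classes. Of 23 members of the DNA methylation machinery 3 were higher and 1 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.751), with a median of −0.0045 while the mean and the test pointed up. The 5-methylcytosine oxidase genes Tet3 and Tet1 had log2 fold changes of 0.76 and −0.77, the repair gene Mbd4 of 0.70, and the methyltransferase gene Dnmt3a did not pass (−0.03). Of 15 MeCP2 partners and Rett-related genes 2 were higher and 1 lower, also when adjusted over the list alone (median 0.09, camera adjusted p = 0.428), namely Foxg1 (0.69), Smarca2 (0.45) and Tbl1x (−0.51). The 5 sex-linked controls had 0 members past the threshold over all genes (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.468).

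Markers of other cells also differed between the cortical wild types. Striatal and subcortical genes were lower in glutamatergic nuclei for 9 of 14 members and higher for 0 (10 and 0 adjusted over the list alone), with a median of −1.39 (camera adjusted p = 1.1e-05, adjusted p = 0.517 with an estimated correlation), and Rgs9, a striatal G-protein regulator, was at 117 against 541 CPM. Summed over this list, the 4 GABAergic libraries held 1406 to 2181 CPM and the 4 glutamatergic libraries 532 to 864. Microglia genes were lower for 4 of 14 members (7 adjusted over the list alone, median −1.62, camera adjusted p = 0.00053, adjusted p = 0.597 with an estimated correlation). Trem2 and Fcrls had log2 fold changes of −2.89 and −2.80. Mitochondrially encoded genes were higher for 2 of 10 members (9 adjusted over the list alone, median 2.43, camera adjusted p = 0.0014, adjusted p = 0.626 with an estimated correlation), and their sum was 479 CPM in glutamatergic wild-type replicate 1, without which the median was 1.24, against 44.4 to 182 CPM in the other libraries. Oxidative phosphorylation genes of the nucleus had 0 of 68 members past the threshold but a median of −0.24 (camera adjusted p = 0.0238, adjusted p = 0.915 with an estimated correlation). Astrocyte and Bergmann glia genes were higher for 1 and lower for 2 of 17 members (2 and 3 adjusted over the list alone, camera adjusted p = 0.0541). Slc1a2 and Slc4a4 had log2 fold changes of 0.85 and −1.20. Camera did not call oligodendrocyte genes (1 higher and 1 lower of 16, 1 and 2 adjusted over the list alone, adjusted p = 0.403), oligodendrocyte precursor genes (0 and 1 of 8, also adjusted over the list alone, adjusted p = 0.119), endothelial and mural genes (1 and 0 of 14, also adjusted over the list alone, adjusted p = 0.407) or cytosolic ribosomal protein genes (0 of 50, also adjusted over the list alone, adjusted p = 0.238). The same held for Purkinje identity (6 higher and 5 lower of 32, 6 and 6 adjusted over the list alone, adjusted p = 0.636) and cerebellar granule genes (5 and 5 of 22, 6 and 7 adjusted over the list alone, adjusted p = 0.961).

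The number of called genes depended on single libraries, at 1624 without GABAergic wild-type replicate 1 and 1578 without glutamatergic wild-type replicate 1. Camera calls near the threshold were also lost, here given as medians. Ionotropic glutamate receptors (−0.26) were not called with DESeq2 size factors (−0.22), without GABAergic wild-type replicate 2 (−0.16) or without glutamatergic replicate 1 (−0.013), and were called at −0.56 without glutamatergic replicate 2. Neurodevelopmental disorder genes (0.20) were not called with library size alone (0.11), without GABAergic replicate 1 (0.19) or without glutamatergic replicate 1 (0.084), and were called at 0.31 without GABAergic replicate 2. Oxidative phosphorylation genes (−0.24) were not called without GABAergic replicate 1 (−0.16) or glutamatergic replicate 2 (−0.21). A pair of genes chosen by the rule for large changes lost their calls in some settings. Anxa1 was higher in glutamatergic nuclei (15.3 ± 18.5 against 0.128 CPM, adjusted p = 0.0142), but lay at 28.4 CPM in replicate 1 and at or below 2.21 CPM in every other cortical library, and lost its call without GABAergic wild-type replicate 1 (adjusted p = 0.111) or replicate 2 (0.0874), with limma-voom (0.0861) and with only the groups compared (0.149). Its log2 fold change was 6.79, between 5.75 and 7.68 in those settings, and 4.01 without glutamatergic wild-type replicate 1, where it was called. Dlx6os1, which lies antisense to Dlx6 so that its counts are uncertain, was at 22.2 ± 15.9 against 476 ± 71.9 CPM (adjusted p = 0.0201) and lost its call without GABAergic wild-type replicate 1 (0.0931), GABAergic replicate 2 (0.0549) or glutamatergic replicate 1 (0.0729), while its log2 fold change of −4.42 was −4.26, −4.57 and −3.83. Scaled by library size alone, 1335 genes were higher and 2049 lower, so that the share of higher calls was 39.5% in place of 49.4%.

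Purkinje and GABAergic wild-type nuclei were compared as inhibitory neurons of different brain regions. Most Purkinje identity, other cerebellar, endothelial and mural genes were higher in Purkinje libraries, and most GABAergic identity, interneuron subclass and striatal genes lower. The GABA synthesis gene Gad1, at 479 against 473 CPM (log2 fold change 0.02), did not pass. The edgeR test called 10648 genes, 4887 higher and 5761 lower in Purkinje nuclei, 7011 of them by more than 1 on the log2 scale. Car8, a regulator of the IP3 receptor, was at 4468 ± 930 against 3.88 CPM, and Grid2, a receptor at parallel fibre synapses, at 7440 ± 395 against 183 CPM.

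Purkinje identity genes were higher for 31 and lower for 1 of 32 members, also when adjusted over the list alone, with a median of 4.55 (camera adjusted p = 4.5e-64, adjusted p = 0.0204 with an estimated correlation). With an estimated correlation, this list in both Purkinje comparisons was the only call that camera kept among all tests of lists. The transcription factor genes Skor2 and Lhx5 were at least 534-fold and 478-fold higher in Purkinje nuclei (51.5 ± 0.25 and 47.5 ± 6.57 CPM against 0 counts in GABAergic nuclei), and the glucose transporter gene Slc5a1 at least 446-fold. Ebf2, a further transcription factor, was higher by a ratio of 1411 (390 to 11660). The meiosis gene Sycp1 was higher by a ratio of 5916 (1637 to 48860). Il22 (ratio 1470, 406 to 12150) and Iltifb (235 ± 27.9 against 0.13 CPM) are near-identical copies whose reads may have been shared, so their separate values are uncertain.

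Most members of the GABAergic identity, interneuron and striatal lists were lower in Purkinje nuclei, some at 0 counts. GABAergic identity genes were lower for 15 and higher for 1 of 18 members, also when adjusted over the list alone, with a median of −6.44, or −5.24 with members at 0 counts set to their bounds (camera adjusted p = 1.9e-07, adjusted p = 0.517 with an estimated correlation). Arx, a transcription factor of forebrain interneurons, was at least 129-fold lower, and Dlx6os1 was lower by a ratio of 2708 (926 to 13130), whereas Gad2 had a log2 fold change of −0.53 (adjusted p = 0.0462) and the vesicular GABA transporter gene Slc32a1 (−0.26) did not pass. Interneuron subclass genes were lower for 19 and higher for 5 of 25 members, also when adjusted over the list alone (median −2.89, camera adjusted p = 9.3e-05, adjusted p = 0.517 with an estimated correlation). Vip had a log2 fold change of −7.19, Chat was at least 42.9-fold lower and Tac2 at least 24.1-fold. Zfp831 was at least 285-fold lower (0 counts against 50.3 ± 6.94 CPM), Eya4 at least 166-fold, Isl1 at least 70.0-fold and Zfp804b at least 61.8-fold. Foxg1, a transcription factor of the forebrain, was lower by a ratio of 707 (127 to 27930). Striatal and subcortical genes were lower for 10 and higher for 3 of 14 members, also when adjusted over the list alone (median −5.76, or −5.52 with bounds, camera adjusted p = 1.0e-05, adjusted p = 0.517 with an estimated correlation).

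Excitatory and activity genes differed as well. Glutamatergic identity genes were lower for 11 and higher for 5 of 20 members, also when adjusted over the list alone (median −1.37, camera adjusted p = 0.0060, adjusted p = 0.597 with an estimated correlation), from Slc30a3 at −6.77 and Ptk2b at −5.82 to Neurod1 at 5.25, while the vesicular glutamate transporter gene Slc17a7 did not pass (−0.02). Cortical layer genes were lower for 16 and higher for 2 of 23 members (16 and 3 adjusted over the list alone, median −1.38, camera adjusted p = 9.1e-06, adjusted p = 0.127 with an estimated correlation), with Satb2 at −4.90 and Crym lower by a ratio of 462 (82.6 to 18250). Immediate early genes were lower for 12 and higher for 3 of 20 members, also when adjusted over the list alone (median −1.82, camera adjusted p = 0.00078, adjusted p = 0.517 with an estimated correlation). Arc was at 3.01 against 55.7 CPM, and Egr3, Npas4 and Fosb had log2 fold changes of −5.28, −4.08 and −4.05.

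Receptor and channel genes differed subunit by subunit. Ionotropic glutamate receptor genes were lower for 11 and higher for 5 of 18 members (12 and 5 adjusted over the list alone, median −1.36, camera adjusted p = 0.0015, adjusted p = 0.328 with an estimated correlation), with the NMDA receptor gene Grin2b at 12.4 against 579 CPM. Of 15 GABA-A receptor genes 9 were lower and 3 higher (9 and 4 adjusted over the list alone, median −1.95, camera adjusted p = 0.0521). Gabrg3 was at −7.25, Gabra5 at −5.28 and Gabra3 at −3.84, whereas Gabra6, the subunit typical of cerebellar granule neurons, was higher by a ratio of 3624 (1002 to 29930) at 234 ± 3.03 CPM. Potassium channel genes were lower for 17 and higher for 6 of 25 members, also when adjusted over the list alone (median −1.55, camera adjusted p = 7.0e-07, adjusted p = 0.196 with an estimated correlation), from Kcnq5 at −7.40 and Kcnc2 at −6.58 to Kcng4 at 213 against 3.12 CPM. Calcium and sodium channel genes were lower for 11 and higher for 6 of 21 members (11 and 7 adjusted over the list alone, median −0.59, camera adjusted p = 0.0003, adjusted p = 0.101 with an estimated correlation). Cacna1h and Scn3a had log2 fold changes of −5.45 and −4.52. Synaptic adhesion genes were lower for 22 and higher for 1 of 27 members (23 and 1 adjusted over the list alone, median −1.23, camera adjusted p = 7.9e-09, adjusted p = 0.0643 with an estimated correlation). Dscaml1 and Cdh13 had log2 fold changes of −4.07 and −3.90. Neurodevelopmental disorder genes were lower for 20 and higher for 5 of 34 members (21 and 6 adjusted over the list alone, median −0.69, camera adjusted p = 0.0011, adjusted p = 0.431 with an estimated correlation). Of the DNA methylation machinery 8 were lower and 3 higher of 23 members, also when adjusted over the list alone (median −0.32, camera adjusted p = 0.735). Mbd4 and Mbd6 had log2 fold changes of 2.34 and −1.93.

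Most nuclear genes of oxidative phosphorylation and most genes of other cerebellar cells were higher in Purkinje nuclei. Oxidative phosphorylation genes were higher for 63 of 68 members and lower for 0, also when adjusted over the list alone (median 1.13, camera adjusted p = 6.9e-11, adjusted p = 0.597 with an estimated correlation). Ndufa1 and Atp5e had log2 fold changes of 2.73 and 2.37. Mitochondrially encoded genes had 0 of 10 members past the threshold, also when adjusted over the list alone (median 0.35, camera adjusted p = 0.705). Cytosolic ribosomal protein genes were higher for 40 of 50 (42 adjusted over the list alone, median 1.23, camera adjusted p = 2.3e-06, adjusted p = 0.710 with an estimated correlation), although their level varied between the Purkinje replicates, with sums of 4219 and 2321 CPM and a median of 0.78 without Purkinje replicate 1. All 14 endothelial and mural genes were higher, also when adjusted over the list alone (median 4.28, camera adjusted p = 0.00044, adjusted p = 0.576 with an estimated correlation), and their sum was 1297 and 664 CPM in the Purkinje libraries against 33.4 to 97.3 CPM in the cortical libraries. Slco1a4, a transporter of brain vessels, was at 204 ± 115 against 3.92 CPM, and the junction gene Cldn5 was higher by 5.59. Astrocyte and Bergmann glia genes were higher for 12 of 17 and lower for 0 (12 and 1 adjusted over the list alone, median 2.02, camera adjusted p = 0.00052, adjusted p = 0.574 with an estimated correlation). Hopx, Aqp4 and Gdf10 had log2 fold changes of 4.70, 3.12 and 3.06. Cerebellar granule and other cerebellar genes were higher for 16 and lower for 5 of 22 members, also when adjusted over the list alone (median 2.22, camera adjusted p = 2.1e-08, adjusted p = 0.127 with an estimated correlation). Cbln3 and Fat2 had log2 fold changes of 9.61 and 8.74. This list summed to 2102 and 2017 CPM in the Purkinje libraries and 642 to 761 CPM in the cortical libraries. Microglia genes were lower for 10 of 14, also when adjusted over the list alone (median −1.85, camera adjusted p = 0.0759). Malat1, a nuclear noncoding RNA chosen after its values were seen, took 8.27% and 8.25% of the counts of the Purkinje libraries and 1.92% to 2.37% elsewhere.

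Cell class, region and other cells cannot be separated here, since every Purkinje library came from the cerebellum. Scaled by library size alone, 3033 genes were higher and 8608 lower (26.1% of calls higher in place of 45.9%), and the median of all genes shifted by −0.381.

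Purkinje and glutamatergic wild-type nuclei gave the largest number of called genes, 11827, with 5655 higher and 6172 lower in Purkinje nuclei and 8076 differing by more than 1 on the log2 scale. Most Purkinje identity, endothelial and mural, and astrocyte and Bergmann glia genes were again higher, and most glutamatergic identity, cortical layer and immediate early genes lower. Car8 was higher by 9.39 and Nrk, a protein kinase, was at 259 ± 7.32 against 0.21 CPM. Satb2 and Tbr1, both transcription factors of cortical excitatory neurons, had log2 fold changes of −8.23 and −6.24.

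Purkinje identity genes were higher for 31 and lower for 1 of 32 members, also when adjusted over the list alone (median 4.71, camera adjusted p = 2.1e-51, adjusted p = 0.0204 with an estimated correlation). Skor2 was at least 478-fold higher, Slc5a1 at least 399-fold, AL772336.1 at least 526-fold, the microRNA gene Mir133b at least 165-fold and Nup62cl at least 89.8-fold, each against 0 counts in glutamatergic nuclei. Lhx5 was higher by a ratio of 642 (177 to 5313) and Cnpy1 by 1316 (450 to 6385). Among interneuron subclass genes 7 were higher and 11 lower of 25 members, also when adjusted over the list alone (median −1.0, or −0.88 with bounds, while the test pointed up, camera adjusted p = 0.949), with Pvalb, a calcium buffer, at 457 ± 245 against 3.85 CPM, Calb2 at 5.83 and Th at 4.63. GABAergic identity genes were higher for 6 and lower for 10 of 18 members, also when adjusted over the list alone (median −3.39, or −2.21 with bounds, camera adjusted p = 0.925). Gad2 had a log2 fold change of 1.97.

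Glutamatergic identity genes were lower for 15 and higher for 2 of 20 members (16 and 2 adjusted over the list alone, median −2.98, camera adjusted p = 1.2e-09, adjusted p = 0.278 with an estimated correlation), led by Slc30a3, a zinc transporter of synaptic vesicles, at −8.77. Cortical layer genes were lower for 17 and higher for 2 of 23 members (18 and 2 adjusted over the list alone, median −3.26, camera adjusted p = 4.7e-08, adjusted p = 0.101 with an estimated correlation), with Crym, Lhx2 and Fezf2 lower by ratios of 830 (149 to 32810), 608 (109 to 24050) and 156 (43.0 to 1293). Foxg1 was lower by a ratio of 1139 (204 to 45000), Zfp831 at least 502-fold, Dkkl1 at least 57.4-fold, Zfp804b at least 47.4-fold and Sh3rf2 at least 44.5-fold. Immediate early genes were lower for 16 and higher for 2 of 20 members, also when adjusted over the list alone (median −3.32, camera adjusted p = 3.4e-09, adjusted p = 0.201 with an estimated correlation). Arc was at 3.01 against 230 CPM and Egr3 at −7.11, while Jun did not pass (−0.02).

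Most genes for channels and adhesion proteins were lower in Purkinje than in glutamatergic nuclei. Potassium channel genes were lower for 15 and higher for 6 of 25 members, also when adjusted over the list alone (median −1.90, camera adjusted p = 8.8e-06, adjusted p = 0.278 with an estimated correlation), from Kcnq5 at −7.74 to Kcng4 at 6.85. Calcium and sodium channel genes were lower for 12 and higher for 9 of 21 members, also when adjusted over the list alone (median −0.66, camera adjusted p = 0.00022, adjusted p = 0.101 with an estimated correlation). Cacna1h and Cacna2d2 had log2 fold changes of −5.30 and 4.03. Synaptic adhesion genes were lower for 23 and higher for 1 of 27, also when adjusted over the list alone (median −1.44, camera adjusted p = 3.4e-08, adjusted p = 0.0643 with an estimated correlation). Ptprd was at 149 against 1678 CPM. Neurodevelopmental disorder genes were lower for 20 and higher for 7 of 34, also when adjusted over the list alone (median −0.79, camera adjusted p = 0.00024, adjusted p = 0.409 with an estimated correlation). Ionotropic glutamate receptor genes were lower for 10 and higher for 4 of 18, also when adjusted over the list alone (median −0.92, camera adjusted p = 0.0521). Grin2b and Grid2 had log2 fold changes of −5.87 and 5.81.

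Endothelial and mural genes were higher for 13 of 14, also when adjusted over the list alone (median 5.93, camera adjusted p = 0.00083, adjusted p = 0.597 with an estimated correlation). Astrocyte and Bergmann glia genes were higher for 14 and lower for 1 of 17, also when adjusted over the list alone (median 2.73, camera adjusted p = 0.00011, adjusted p = 0.565 with an estimated correlation), and Slc1a3, a glutamate transporter of glia, was at 432 against 33.3 CPM. Cerebellar granule and other cerebellar genes were higher for 15 and lower for 4 of 22 (16 and 4 adjusted over the list alone, median 3.39, camera adjusted p = 3.8e-07, adjusted p = 0.120 with an estimated correlation). Gabra6 and Cbln3 had log2 fold changes of 10.58 and 9.02. Oxidative phosphorylation genes were higher for 64 of 68, also when adjusted over the list alone (median 1.5, camera adjusted p = 2.8e-12, adjusted p = 0.574 with an estimated correlation). Mitochondrially encoded genes were lower for 2 of 10 members, also when adjusted over the list alone, and all 10 were negative (median −2.16, camera adjusted p = 0.42). Microglia genes were lower for 1 and higher for 0 of 14, also when adjusted over the list alone (median −0.58, camera adjusted p = 0.886). Cytosolic ribosomal protein genes were higher for 40 and lower for 1 of 50, also when adjusted over the list alone (median 0.97, camera adjusted p = 0.00031, adjusted p = 0.801 with an estimated correlation), with a median of 0.52 without Purkinje replicate 1. Striatal and subcortical genes were lower for 9 and higher for 3 of 14, also when adjusted over the list alone (median −3.57, or −3.03 with bounds, camera adjusted p = 0.0077, adjusted p = 0.668 with an estimated correlation). Region, class and other cells are again inseparable. Scaled by library size alone, 4081 genes were higher and 7918 lower (34.0% of calls higher in place of 47.8%), with a shift of −0.297 in the median of all genes.

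GABAergic nuclei from mice labelled MeCP2 KO were compared with wild type to ask which transcripts differ with the labelled genotype in inhibitory neurons. No single gene passed, and the clearest pattern was a set of small differences toward higher values among immediate early genes. Of 20 immediate early genes 19 had positive differences, with a median of 0.81 (camera adjusted p = 6.2e-26, adjusted p = 0.0643 with an estimated correlation), and 12 passed when adjusted over the list alone against 0 over all genes. The differences were 1.52 for the nuclear receptor gene Nr4a3, 1.17 for Fos, 1.16 for Btg2, 1.10 for Fosb, 1.03 for Junb and 1.02 for Fosl2, all chosen after their values were seen. Arc was at 103 against 55.7 CPM (0.89, SE 0.24, adjusted p = 0.651). Summed over the list, the libraries labelled MeCP2 KO held 1346 and 1488 CPM and the wild-type libraries 1068 and 742.

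**Figure D3:**
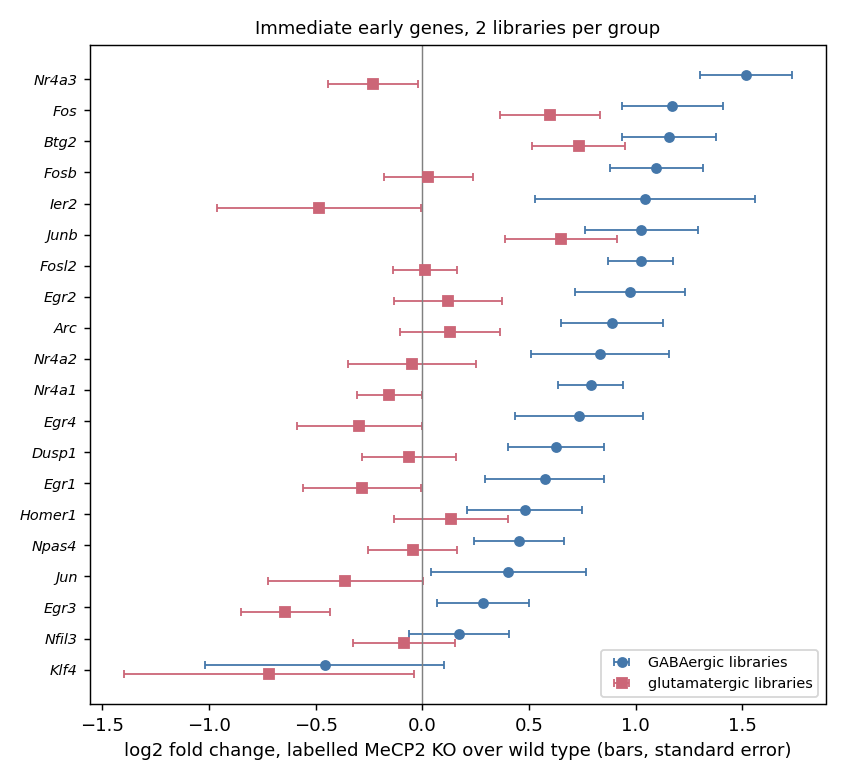
Log2 fold change of 20 immediate early genes, libraries labelled MeCP2 KO over wild type, in GABAergic and glutamatergic nuclei, with bars for the standard error from 2 libraries per group. In GABAergic nuclei 19 of 20 genes lay above 0 with a median of 0.81, and in glutamatergic nuclei the median was −0.06.

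The edgeR test called 0 genes in GABAergic nuclei, with a smallest adjusted p of 0.118, while 1499 genes had an unadjusted p below 0.05 where 991 would be expected by chance. DESeq2 called 22 genes and limma-voom 0, and the edgeR test without the filter called 196. Among the genes that DESeq2 called, chosen after their values were seen and given with the log2 fold changes of DESeq2, were Nr4a3 (1.53), Fosl2 (1.03), Irak1 (1.18), the sodium pump gene Atp1a1 (0.87) and the axon guidance receptor gene Robo3 (−1.64). Without GABAergic wild-type replicate 1 the edgeR test called 7 genes.

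Other lists stood apart from the remaining genes by small medians with 0 members past the threshold over all genes. Cytosolic ribosomal protein genes had a median of 0.42 (camera adjusted p = 4.0e-14, adjusted p = 0.554 with an estimated correlation) and oxidative phosphorylation genes of 0.31 (1.7e-14, adjusted p = 0.539 with an estimated correlation), both with 0 members adjusted over the list alone. Atp5a1, a subunit of ATP synthase, was at 276 against 170 CPM. Reported MeCP2-responsive genes had a median of 0.20 (camera adjusted p = 0.0017, adjusted p = 0.127 with an estimated correlation) with 1 member adjusted over the list alone, and of 0.12 without the library labelled MeCP2 KO replicate 1. Synaptic adhesion genes had a median of 0.17 (0.00053, adjusted p = 0.101 with an estimated correlation) and GABA-A receptor genes of 0.21 (0.0019, adjusted p = 0.127 with an estimated correlation), where Gabra1 was at 265 against 192 CPM and the median was 0.36 without wild-type replicate 1. GABAergic identity genes had a median of −0.03 (0 members adjusted over the list alone, camera adjusted p = 0.961).

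Several further lists were called only with certain libraries. Glutamatergic identity genes (median 0.32, 1 member adjusted over the list alone, camera adjusted p = 0.0002, adjusted p = 0.517 with an estimated correlation) had medians of 0.039 without the GABAergic library labelled MeCP2 KO replicate 1 and 0.20 without wild-type replicate 1, neither called, and of 0.61 without the library labelled MeCP2 KO replicate 2. Leaving out either of the first 2 libraries ended the calls of interneuron subclass genes (median 0.24, adjusted p = 0.0109, medians of 0.015 and 0.077), potassium channel genes (0.10, 0.0269, 0.041 and 0.030), granule genes (0.20, 0.0288, 0.12 and 0.10) and cortical layer genes (0.19, 0.0386, 0.15 and 0.25). With an estimated correlation these had adjusted p = 0.654, 0.483, 0.539 and 0.454. Without wild-type replicate 2 these 5 lists had medians of 0.59, 0.42, 0.18, 0.27 and 0.10, all called. Microglia genes had a median of 0.53 (camera adjusted p = 0.0166, adjusted p = 0.721 with an estimated correlation), which lost its call without wild-type replicate 1 (median 0.47), and their sum was 435 CPM in the library labelled MeCP2 KO replicate 1 against 170, 195 and 204 CPM in the other GABAergic libraries. Without that library the microglia median was −0.27, and the oligodendrocyte median of 0.29 (0.0365, adjusted p = 0.801 with an estimated correlation) became −0.17. Without the library labelled MeCP2 KO replicate 2 they were 1.13 and 0.53. Striatal and subcortical genes (0.28, 0.0256, adjusted p = 0.721 with an estimated correlation) had medians of 0.18 without the library labelled MeCP2 KO replicate 2 and 0.017 without wild-type replicate 2, neither called, and of 0.53 without wild-type replicate 1. With the 8 cortical libraries alone the calls of granule (median 0.18), cortical layer (0.20), oligodendrocyte (0.29), potassium channel (0.10) and striatal genes (0.28) were lost at nearly the same medians.

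Glutamatergic nuclei from mice labelled MeCP2 KO were compared with wild type to ask the same of excitatory neurons. A single gene passed, Irak1, which encodes a kinase of interleukin-1 signalling and lies next to Mecp2. Irak1 was at 189 ± 17.2 against 47.4 ± 9.27 CPM (log2 fold change 1.99, SE 0.18, adjusted p = 0.0022), higher in both libraries labelled MeCP2 KO than in either wild type. In GABAergic nuclei Irak1 was at 131 ± 0.96 against 58.6 ± 13.8 CPM (1.16, SE 0.18, adjusted p = 0.127). Irak1 is the member past the threshold among 25 reported MeCP2-responsive genes, also when adjusted over the list alone (median 0.03, camera adjusted p = 0.0927). The ubiquitin ligase gene Ube3a was at 1007 against 747 CPM (0.43, adjusted p = 0.580), which did not pass.

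At an unadjusted p below 0.05 there were 1626 genes where 991 would be expected by chance, and 1 adjusted call by limma-voom, 26 by DESeq2 and 414 by the edgeR test without the filter. Of the 26 genes, 18 were lower in the libraries labelled MeCP2 KO, and 10 of the 18 were more than 2-fold higher in wild-type replicate 1 than in replicate 2. Among the 26 were Ltf, S100a9, Ngp, Prtn3, Cybb and Anxa1, chosen after their values were seen, which were highest in wild-type replicate 1 of all cortical libraries. Without glutamatergic wild-type replicate 2 the edgeR test called 115 genes, without wild-type replicate 1 it called 3, and without the library labelled MeCP2 KO replicate 2 it called 2. Of the 115, 89 were tested with all libraries and 80 of these were lower in the libraries labelled MeCP2 KO, and 70 of the 80 were more than 2-fold higher in wild-type replicate 1 than in replicate 2.

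Among the lists, mitochondrially encoded genes had a median of −2.07 with all 10 members negative and 0 past the threshold, also when adjusted over the list alone (camera adjusted p = 2.3e-06, adjusted p = 0.517 with an estimated correlation). In wild-type replicate 1 they summed to 479 CPM, against 44.4 to 182 CPM in the other libraries, and without it the median was −0.79. Oxidative phosphorylation genes had a median of 0.17 (camera adjusted p = 9.3e-05, adjusted p = 0.774 with an estimated correlation) and synaptic adhesion genes of 0.10 (0.0490, adjusted p = 0.328 with an estimated correlation), both with 0 members past the threshold, also when adjusted over the list alone. The call of synaptic adhesion genes was lost, at medians that moved little, with DESeq2 size factors (0.10), library size alone (0.086), the age term (0.10) and the 8 cortical libraries (0.098). It was also lost without the library labelled MeCP2 KO replicate 1 (0.15), wild-type replicate 1 (0.11) or wild-type replicate 2 (0.14). Endothelial and mural genes had a median of 0.98 (0.0062, adjusted p = 0.667 with an estimated correlation) but were not called without the library labelled MeCP2 KO replicate 2 (median 0.025) or wild-type replicate 2 (1.22), and had a median of 1.68 without the library labelled MeCP2 KO replicate 1. Immediate early genes had a median of −0.06 (camera adjusted p = 0.974). Purkinje identity genes had 2 higher and 5 lower members adjusted over the list alone and 0 over all genes (camera adjusted p = 0.19).

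The KO effects of both cortical classes were then compared directly, as glutamatergic minus GABAergic effect. The immediate early genes differed, with all 20 members lower in this contrast and a median of −0.81 (camera adjusted p = 4.9e-23, adjusted p = 0.0707 with an estimated correlation), 5 of them adjusted over the list alone and 0 over all genes. Mecp2 differed by 0.25 (adjusted p = 1), which the test could not separate from 0. The edgeR test called 0 genes, with 425 at an unadjusted p below 0.05 where 991 would be expected, against 0 by limma-voom, 4 by DESeq2 and 108 by the edgeR test without the filter. Without glutamatergic wild-type replicate 2 it called 14 genes.

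Across the 19822 genes tested, which are not independent replicates, the log2 effects in both classes had a Pearson correlation of 0.203 and a Spearman correlation of 0.364, and 65.3% had the same sign. At an unadjusted p below 0.05, 108 genes were higher in both, where independent lists of 791 and 613 genes would share 24.5, and 164 were lower in both, where lists of 708 and 1013 would share 36.2. These comparisons share no libraries but share each gene's fitted spread, so 24.5 and 36.2 are not chance levels. Other groupings can give a like size. The glutamatergic effect had Spearman correlations of −0.369 with GABAergic older against younger mice and 0.373 with the labelled genotypes on that scale. With a single library left out the Spearman correlation lay between 0.117 and 0.427. It was 0.117 without GABAergic wild-type replicate 2, 0.211 without the GABAergic library labelled MeCP2 KO replicate 2 and 0.232 without glutamatergic wild-type replicate 2.

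Long genes were tested because MeCP2 loss has been linked to their higher expression. The 2338 tested genes with a span over 100 kb stood above the 15260 others by a median log2 difference of 0.022 in GABAergic nuclei (camera p = 0.183, p = 0.347 with an estimated correlation) and 0.077 in glutamatergic nuclei (camera p = 0.0065, p = 0.0881 with an estimated correlation). In glutamatergic nuclei the same value was 0.0041 and −0.0056 between the replicates of a group and 0.0073 and 0.0101 for the other ways of pairing the 4 libraries. In GABAergic nuclei it was −0.109 and 0.062 between replicates and −0.084 and −0.030 for the other pairings, larger than the value for the genotypes. Without the GABAergic library labelled MeCP2 KO replicate 1 the GABAergic difference was 0.0730 and was called, without the library labelled MeCP2 KO replicate 2 it was −0.0215, and without wild-type replicate 2 it was −0.0097. Without the glutamatergic library labelled MeCP2 KO replicate 1 the glutamatergic difference was 0.0801 and was no longer called. The difference between the classes was 0.052, which camera did not call.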

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

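The KO effect differed between the cortical classes, by camera on the difference of effects (glutamatergic minus GABAergic), for 11 of the 26 lists, each given here as a median log2 difference. Both tests of explanations in this part were chosen only after the result was seen. In these lists 0 genes were past the threshold over all genes. None of the 11 was called with an estimated correlation, where the adjusted p ranged from 0.0707 to 0.845.

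Immediate early genes differed by −0.81, with all 20 members negative. Cytosolic ribosomal protein genes differed by −0.43, with all 50 members negative (adjusted p = 0.574 with an estimated correlation). Glutamatergic identity genes differed by −0.40 (adjusted p = 0.517 with an estimated correlation), which was −0.041 without the GABAergic library labelled MeCP2 KO replicate 1 and −0.14 without GABAergic wild-type replicate 1, neither called. Oxidative phosphorylation genes differed by −0.17 (adjusted p = 0.845 with an estimated correlation), and cortical layer genes by −0.15 (adjusted p = 0.424 with an estimated correlation). Purkinje identity genes differed by −0.19 (adjusted p = 0.574 with an estimated correlation), and voltage-gated potassium channel genes by −0.092 (adjusted p = 0.454 with an estimated correlation). Striatal and subcortical genes differed by −0.21 (adjusted p = 0.710 with an estimated correlation), which became 0.079 without GABAergic wild-type replicate 2 and 0.16 without the glutamatergic library labelled MeCP2 KO replicate 2. Mitochondrially encoded genes differed by −1.91 (adjusted p = 0.488 with an estimated correlation), and their sum was highest, at 479 CPM, in glutamatergic wild-type replicate 1. Endothelial and mural genes differed by 1.34 (adjusted p = 0.667 with an estimated correlation), which became −0.0076 without GABAergic wild-type replicate 1. Microglia genes differed by −0.89 (adjusted p = 0.628 with an estimated correlation), which became 0.28 without the GABAergic library labelled MeCP2 KO replicate 1, whose microglia sum of 435 CPM was the highest of the GABAergic libraries.

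Immediate early, cytosolic ribosomal protein and mitochondrially encoded genes kept their camera call without each single library, with medians of −0.57 to −0.99, −0.26 to −0.59 and −0.77 to −2.98, and the other 8 lists lost it without some libraries. Without the GABAergic library labelled MeCP2 KO replicate 1 the call was also lost for oxidative phosphorylation (−0.062), cortical layer (−0.062), potassium channel (−0.080) and endothelial genes (1.32), and without its replicate 2 for Purkinje identity (−0.066) and striatal genes (−0.038). Without GABAergic wild-type replicate 1 potassium channel genes (−0.11) were not called, nor were oxidative phosphorylation (−0.077), cortical layer (−0.21) and Purkinje identity genes (−0.042) without its replicate 2. Without the glutamatergic library labelled MeCP2 KO replicate 1 these were oxidative phosphorylation (−0.098), Purkinje identity (−0.25) and potassium channel genes (−0.15). Without its replicate 2 they were cortical layer (−0.14), Purkinje identity (−0.13), potassium channel (−0.053), microglia (−0.31) and endothelial genes (0.42). Without glutamatergic wild-type replicate 1 they were oxidative phosphorylation (−0.096) and potassium channel genes (−0.083), and without its replicate 2 cortical layer (−0.21), Purkinje identity (−0.028), striatal (−0.043) and endothelial genes (1.58). Purkinje identity genes were also not called with the 8 cortical libraries (−0.087) or the age term (−0.19).

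The immediate early gene pattern came from the GABAergic libraries, where 19 of 20 members were higher in the libraries labelled MeCP2 KO. Since glutamatergic nuclei hold more of these transcripts, RNA from glutamatergic neurons could raise them, but the 18 glutamatergic identity genes gave a median share of 5.52% of such RNA (quartiles 1.77% to 22.1%), below the 40.0% (30.8% to 69.8%) that 15 early genes would need. By replicate the identity genes gave 16.2% and −2.47% and the early genes 48.8% and 37.9%, which argues against that source. Age was also argued against, because the median log2 difference was 0.69 in the mice of 5 to 6 weeks and 0.86 in those of 6 to 7 weeks, with 19 of 20 members higher in each pair of libraries. A genotype effect on activity-induced transcription in GABAergic neurons is a hypothesis that stays open, as do differences between mice in handling or activity before tissue collection, which no table here can test.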

How the results depend on the processing

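Named genes and lists kept their direction under both other scalings. Under each of these, 132 of 134 also kept their side of the threshold and 2 lost it, synaptic adhesion genes in the glutamatergic KO comparison under both. Against 62 kept and 1 lost under limma-voom, 62 and 1 with only the groups compared, and 63 and 0 with the stricter filter, an estimated correlation kept 2 list calls and ended 69. DESeq2 kept 56 and added 7, and the edgeR test without the filter kept 51 and added 12. The 8 cortical libraries alone kept 37 and lost 7, and the age term kept 42 and lost 2, both for lists and fits partly added after the data were seen. In simulated GABAergic KO libraries of this depth and number, 6% of genes changed 1.5-fold and 44% changed 2-fold were recovered, and other depths and numbers were not simulated.

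DESeq2 called 22 genes in the GABAergic, 26 in the glutamatergic and 4 in the difference of KO effects, where the edgeR test called 0, 1 and 0, and called Mecp2 at 0.77 (adjusted p = 0.0015) and 1.02 (adjusted p = 1.6e-06). Without the filter the edgeR test called 196, 414 and 108 genes, Mecp2 at 0.77 (adjusted p = 0.0019) and 1.02 (adjusted p = 3.0e-07), and the Spearman correlation of KO effects was 0.22, against 0.364 with the filter. All 196 and 375 of the 414 genes were also tested with the filter. Without it 29055 genes were fitted and the median prior degrees of freedom were infinite, against 7.42 with it, but no fit separated this from the larger set of genes. In simulated GABAergic libraries the fit without the filter gave 26.9% false calls, against 8.46% with it and 13% for DESeq2. The glmTreat test against 0.5, a stricter null, called 1469 genes between the cortical wild types. At a 200 kb limit the GABAergic long-gene difference of 0.0436 passed, but not with an estimated correlation (camera p = 0.171). Otherwise the cause was not tested.

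Leaving out each library in turn gave 1578 to 2933 called genes between glutamatergic and GABAergic wild type, 8261 to 9805 between Purkinje and GABAergic and 10208 to 10627 between Purkinje and glutamatergic. It gave 0 to 7 in GABAergic and 1 to 115 in glutamatergic KO comparisons, 0 to 14 for the difference of KO effects and 1 to 286 for the average KO effect. Mecp2 ranged from 0.59 to 0.92 (adjusted p from 0.124 to 1) and from 0.95 to 1.07 (0.0467 to 0.419), and the Spearman correlation of KO effects from 0.117 to 0.427. The long-gene difference ranged from −0.0215 to 0.0730 in GABAergic and from 0.0669 to 0.0812 in glutamatergic nuclei.

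Signs turned without single libraries. Without the GABAergic library labelled MeCP2 KO replicate 1, microglia genes were at −0.27 and oligodendrocyte genes at −0.17 in the GABAergic KO comparison, and microglia genes at 0.28 in the difference (over all libraries left out in turn, from −0.27 to 1.13, from −0.17 to 0.53 and from −1.97 to 0.28). Without its replicate 2 the GABAergic long-gene difference was −0.0215. Without GABAergic wild-type replicate 1, oligodendrocyte genes were at −0.018 in the GABAergic KO comparison, and endothelial genes at −0.0076 in the difference (from −0.0076 to 1.93). Without GABAergic wild-type replicate 2 the long-gene difference was −0.0097 and striatal genes were at 0.079 in the difference, and without the glutamatergic library labelled MeCP2 KO replicate 2 striatal genes were at 0.16 (from −1.01 to 0.16). The cause was not tested.

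With the replicate number as a block, the edgeR test called 3007, 10321 and 11590 genes between the wild types and 0, 1 and 0 in the KO comparisons and their difference. Of 134 results, again with the number of calls for the average KO effect, 129 kept their side of the threshold. The other 5 lost their call at nearly the same values: Dlx6os1 (−4.41), ionotropic glutamate receptors (−0.26) and neurodevelopmental disorder genes (0.19) between glutamatergic and GABAergic wild type, synaptic adhesion genes in the glutamatergic KO comparison (0.094) and Purkinje identity genes in the difference (−0.19). The number names samples only, since the labels tie it to no shared day or litter, and deviations of same-numbered libraries correlated at −0.398 to 0.274 across genes.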

Other observations

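Gene groups that the account of the Purkinje comparisons left out held members that differed in both directions, where 10648 and 11827 of 19822 genes were called, and camera called none of these groups. Among 15 MeCP2 partners and Rett-related genes, 5 were higher and 6 lower in Purkinje than in GABAergic nuclei, and likewise than in glutamatergic nuclei, also when adjusted over the list alone (camera adjusted p = 0.54 and 0.38). Cdkl5, a kinase gene mutated in an early epilepsy, had log2 fold changes of −2.34 and −2.75, the corepressor gene Ncor2 of −1.61 and −2.42, and the chromatin remodeller gene Atrx of 0.58 and 0.75. Of 25 reported MeCP2-responsive genes, 8 were higher and 11 lower than in GABAergic nuclei, and 10 were higher and 11 lower than in glutamatergic nuclei (8 and 11, then 10 and 12, adjusted over the list alone; camera adjusted p = 0.705 and 0.942). In the last case the median was −0.73 while the test pointed up. Oligodendrocyte genes were higher for 3 and lower for 1 of 16 members than in GABAergic nuclei and higher for 6 and lower for 2 than in glutamatergic nuclei (3 and 0, then 5 and 2, adjusted over the list alone; camera adjusted p = 0.4545 and 0.278), with Ugt8a at 1.87 and 2.57. Cbln2 was the member of the Purkinje identity list that was lower, at −3.66 and −4.49. Of the genes in this paragraph, Ncor2, Atrx and Cbln2 were named after their values were seen.

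The average KO effect over both cortical classes, added after the data were seen, had 3 called genes in the edgeR test: Irak1 (1.58, adjusted p = 0.00051), Gm8545 (3.56, adjusted p = 0.0068) and Mecp2 (0.89, adjusted p = 0.0074). At an unadjusted p below 0.05 there were 2839 genes, and DESeq2 called 165 and limma-voom 3. The count was 286 without GABAergic wild-type replicate 1, 27 without glutamatergic wild-type replicate 2 and 1 without the GABAergic library labelled MeCP2 KO replicate 2. Of 34 splits of the 8 cortical libraries into 4 and 4, 6 called as many genes, the real split counted in both numbers, so that chance cannot be excluded for the count. The real split called 3 genes and the highest other split 115, for a cause that was not tested. That split set both GABAergic libraries labelled MeCP2 KO, GABAergic wild-type replicate 1 and the glutamatergic library labelled MeCP2 KO replicate 2 against the rest. It therefore followed the labelled genotypes in large part.

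Tests of explanations here followed patterns already seen. Only the granulocyte, whole-blood and split tests were set before their values were seen. Mecp2 and Irak1 were higher in the libraries labelled MeCP2 KO, where a loss of the target would lower Mecp2. Exchange of single libraries was not decided, since its test restates the pattern (lowest labelled MeCP2 KO 202 CPM, highest cortical wild type 137 CPM). Scaling was argued against by a smallest log2 difference of Mecp2 of 0.717 under the other scalings. An exchange of the genotype labels in both classes stays open: Mecp2 in the cortical wild types lay 0.18 above Purkinje wild type on the log2 scale, but cell types may differ in Mecp2, so the value does not decide. For a change confined to the edited locus, 0 of 18 other neighbours were higher in both classes at an unadjusted p below 0.05, although at that level Flna was lower in both (−0.68 and −0.49) and Emd (0.57), Rpl10 (0.45) and Atp6ap1 (0.32), named after their values were seen, were higher in GABAergic nuclei. A candidate explanation that stays open is a transcript of the edited allele that keeps exons counted for Mecp2 and affects the adjacent Irak1, which exon-level reads, not analysed here, could test.

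Glutamatergic wild-type replicate 1 held transcripts of neutrophil granules, with Ngp at 234 CPM, S100a9 at 180, Ltf at 166 and S100a8 at 129, against at most 0.644, 0.119, 0.0654 and 0.127 CPM in the other cortical libraries. RNA from granulocytes or their precursors may be the source, since 22 of 23 granulocyte genes (95.7%), from a list written before the test, were highest in this library. For whole blood, haemoglobin genes reached 16.6 CPM, 9.18% of S100a9, close to the bound of 10% set beforehand but no higher than the 18.7 CPM of another cortical library. The libraries came from purified nuclei, which mature red blood cells lack, so this value does not decide on whole blood. Microglia were argued against by a median log2 difference of −0.12 from replicate 2 over 14 microglia genes. Purification of GFP-tagged nuclei is meant to leave out such cells, but the values here do not show that it did. No biological explanation was tested.

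Single transcripts, chosen after their values were seen, also stood apart in single libraries. AY036118 was at 9559 CPM in glutamatergic wild-type replicate 1 and 387 to 1163 CPM elsewhere. Gm10800 was at 2205 CPM in GABAergic wild-type replicate 2 and 2180 CPM in Purkinje replicate 1, and at or below 23.7 CPM elsewhere.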
